A study of Homo sapiens with 12 samples.

How the data were processed

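Polyadenylated RNA of NCI-H295R cells was sequenced in 12 libraries, 4 groups of 3 biological replicates per the labels. The authors aligned reads with STAR to hg38 and counted them with featureCounts; no versions are given, and the annotation release, the strand setting and the handling of multimapping reads are not given in the sources used here. The deposited table holds estimated counts (expected counts, many of them fractional) for 60617 Ensembl genes, and 65.6% of its non-zero values are whole within 1e-06. It also holds a gene length column deposited by the authors, of another unit, which was used only to test length bias. All 12 count columns were matched to the labels by name, with 0 left over. Symbols were available for 60261 genes. Gene positions were taken from GENCODE release 29.

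Counts were rounded and analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr with the 4 groups, which left 20360. Libraries were scaled by TMM (trimmed mean of M values), and CPM in the text are TMM-scaled means with the SD of 3 libraries. A single quasi-likelihood model with robust dispersion was fitted to all 12 libraries, and each of the 6 pairs of groups was tested within it. P-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. They measure the spread between replicate cultures of 1 cell line. A test against a fold of 1.5 (glmTreat) gave the genes changed by more than that. The SE of a log2 fold change was computed as its size divided by the square root of F. The common dispersion was 0.00248, a biological coefficient of variation of 5%, and the median prior degrees of freedom 11.5. Library totals were 20.6 to 31.5 megacounts. Replicate pairs were set against counting noise alone with a chi-square per degree of freedom over genes with at least 100 counts.

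Each of 33 fixed gene lists was tested with camera on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, adjusted over the lists and the 3 comparisons with baseline. An estimated correlation was run beside it, since a preset value can be too small for genes that move together. Counts of members were also adjusted over the list alone. Calls were compared between treatments by their direction, against independent lists of the same sizes and against 20 simulated sets of 4 unchanged groups, in which the baseline libraries were drawn as well and shared by the comparisons.

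The genes named for a comparison with baseline follow a rule. It takes the 8 largest rises and 8 largest falls among genes that passed, with a mean log2 CPM of at least 1 and no overlap between the 3 libraries of either group, a separation that chance gives in 10% of genes. It adds up to 4 members of each list described with the largest changes, the members that go against a list, and a fixed set of steroidogenic, Wnt, Polycomb and proliferation genes. Comparisons between treatments name the fixed set and the 5 largest in each direction. The text names some of the genes this rule selects, and results for the others are not reported here. Other members of a list are named only where they did not pass in a list that moved as a whole. The comparisons, tests, lists, naming rule and most alternatives were chosen before the data were examined. The list tests between treatments, adjusted over 33 lists and 3 comparisons, were chosen afterwards.

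Alternatives were DESeq2 1.42.0, limma voom, other scalings (RLE, upper quartile, library size only), other filters (no filter, or at least 1 CPM in at least 3 libraries), fits of only the 2 groups compared, each library left out in turn, a fold threshold of 2, fry and a prior count of 0.5. The pipeline was tested on simulated data made like the EZH2i and baseline libraries, with 50 genes changed at each fold. It recovered 27 at 1.25-fold, 43 at 1.5-fold, 50 at 2-fold and 50 at 4-fold. The test against 1.5-fold called 0, 0, 39 and 50 of these. Of all calls 5.03% were unchanged genes (9 genes), and 1 gene was called in an unchanged group. All 10 raised lists of 30 genes were called and 0 of 10 unchanged lists. The simulated genes were drawn independently, so this does not test the preset correlation for genes that move together. Only a small part of the simulated genes was changed, against 50.6% to 58.9% in the comparisons with baseline. Scaling and false calls under such wide changes were therefore not tested. Reads were not realigned, so splicing, isoforms and strand were not examined.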

Results

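NCI-H295R is an established human adrenocortical carcinoma cell line that makes steroid hormones. Polyadenylated RNA was sequenced from 4 groups of these cells, with 3 biological replicates per group and 12 libraries in all. The baseline group received DMSO, the vehicle, for 96 h. The EZH2i group received 62 µM EPZ-6438 for 96 h, an inhibitor of EZH2, the histone methyltransferase of the Polycomb complex PRC2. The CBPi group received 26 µM PRI-724 for 96 h, which blocks the binding of the coactivator CBP to β-catenin, so an effect on the acetyltransferase activity of CBP is not implied. The labels give both inhibitor doses as IC50 doses. The FSK group received vehicle for 48 h and then 10 µM forskolin, which activates adenylyl cyclase and raises cAMP, for 48 h. Every group was in culture for 96 h, so exposure to forskolin was shorter than exposure to either inhibitor.

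Total counts per library, in megacounts, were 21 to 27 at baseline, 29.5 to 31.5 with EZH2i, 20.6 to 28.8 with CBPi and 23.4 to 25.4 with FSK. Replicates had Pearson correlations of 0.992 to 0.996 across genes on log2 CPM, TMM-scaled counts per megacount, and libraries of different groups 0.953 to 0.982. Genes are not independent replicates, so these correlations only describe the libraries. The first 3 principal components held 46.8%, 22.6% and 14.2% of the variance, and the 4 groups lay apart on them. Every pair of replicates differed by more than counting noise. The chi-square per degree of freedom was 13.2 and 12.1 for the pairs with CBPi replicate 2, and 2.56 to 6.68 for the other 10 pairs. Mitochondrially encoded genes took 2.74% ± 0.44 of counts at baseline, 3.76% ± 0.58 with EZH2i, 4.11% ± 0.64 with CBPi and 2.94% ± 0.29 with FSK (SD, n = 3).

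The first comparison asked what 62 µM EPZ-6438 did to the transcriptome, and genes of steroid synthesis fell. No histone mark was measured, so the results of EZH2 inhibition and other effects of this dose cannot be told apart. HSD3B2, a dehydrogenase needed for all active steroid hormones, went from 78.5 ± 6.6 CPM at baseline to 3.94 ± 0.75 CPM (SD, n = 3). That is 19.8-fold lower (log2 fold change -4.31 ± 0.09 SE, adjusted p = 2.42e-18, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). STAR, which moves cholesterol into mitochondria, fell from 661 ± 8.8 to 162 ± 4.8 CPM. CYP11A1, which makes pregnenolone from cholesterol, fell from 309 ± 12 to 50.2 ± 0.72 CPM, and CYP17A1, needed for cortisol and androgens, from 63.4 ± 2.9 to 13.1 ± 0.35 CPM. Of 16 steroidogenic enzymes tested, 14 fell and 0 rose, with a median log2 fold change of -1.75. CYP11B1 (-0.64) and AKR1C3 (0.13) did not pass, though AKR1C3 was higher when adjusted over the list alone. CYP11B1 had raw counts of only 10, 12 and 9 at baseline and 11, 5 and 10 with EZH2i, so a fall could be missed. The list passed camera (adjusted p = 1.71e-08, and adjusted p = 0.0472 with an estimated correlation). NR5A1, the nuclear receptor that drives steroidogenic genes, fell from 588 ± 6.3 to 351 ± 7.8 CPM. Its repressor NR0B1 rose from 10.3 ± 1.2 to 20.4 ± 1.8 CPM. In the adrenocortical identity list, 11 of 16 genes fell, among them the ACTH receptor MC2R (3.53 ± 0.54 to 0.99 ± 0.11 CPM), while CITED2, HOXA5, NR0B1 and TBX3 rose (camera adjusted p = 0.00875, and adjusted p = 0.218 with an estimated correlation). Among 17 zona glomerulosa genes, markers of the aldosterone-making layer, 10 fell and 5 rose, such as NR4A2, SHH, KCNK9 and CACNA1H (adjusted p = 0.0319, and 0.218 as the adjusted p with an estimated correlation).

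**Figure D1:**
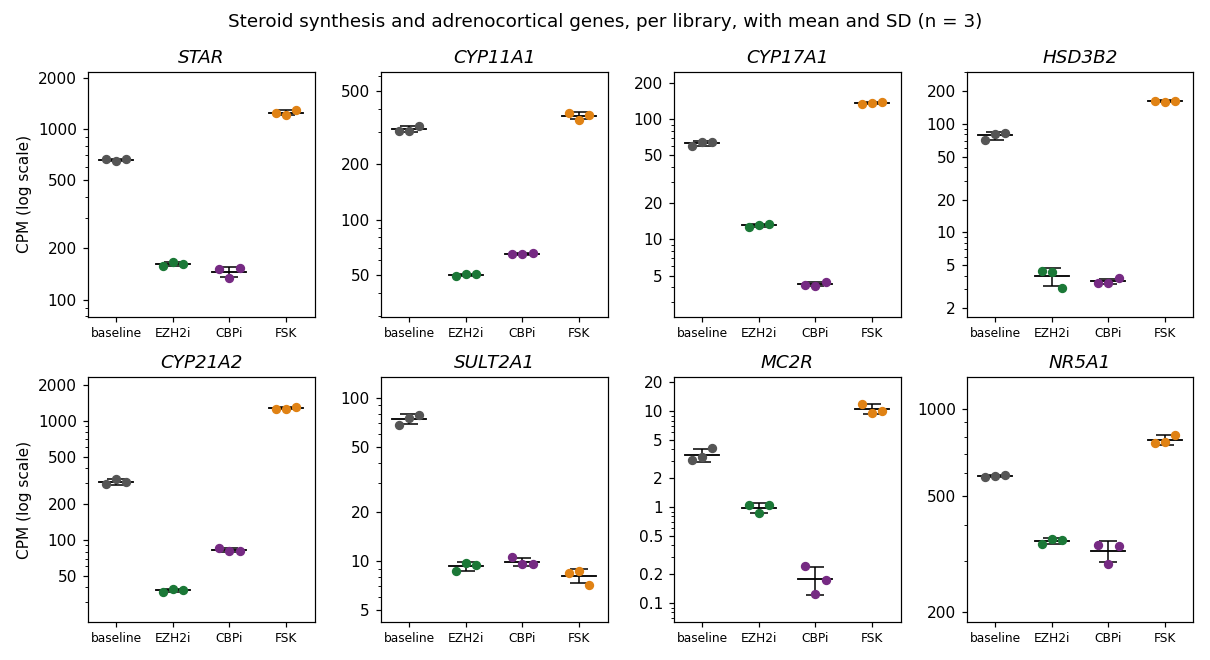
CPM of 8 genes on log scales, 1 point per library, with the mean and SD of each group (n = 3). STAR was at 661 ± 8.8 CPM at baseline, 162 ± 4.8 with EZH2i, 146 ± 10 with CBPi and 1240 ± 43 with FSK, while SULT2A1 was lower than at baseline in all 3 treated groups.

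Wnt target genes and genes that Polycomb silences in many cell types rose with EZH2i. CCND1, which encodes cyclin D1, went from 2.24 ± 0.067 to 22.6 ± 0.23 CPM, 10-fold higher (log2 fold change 3.33 ± 0.11 SE). The Wnt feedback inhibitors NKD1 and AXIN2 rose from 353 ± 26 to 1290 ± 50 CPM and from 103 ± 4.6 to 193 ± 3.3 CPM, and the transcription factor LEF1 rose from 93.1 ± 2.9 to 198 ± 9.4 CPM. Of 22 Wnt targets tested, 16 rose, and BIRC5, WIF1 and ISM1 fell (camera adjusted p = 6.01e-06, and adjusted p = 0.188 with an estimated correlation). CTNNB1, which encodes β-catenin, fell from 1280 ± 23 to 971 ± 19 CPM. The mRNA of EZH2 itself was at 94.8 ± 2.3 CPM at baseline and 97.2 ± 1.4 CPM with EZH2i and did not pass (adjusted p = 0.474, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). EED fell by 0.54 and SUZ12 by 0.24 on the log2 scale, and EZH1 rose by 0.31. Of 50 developmental Polycomb targets outside the HOX clusters, 30 rose, such as MSX2 (5.89 ± 0.53 to 76.5 ± 2.9 CPM) and FOXF1 (1.33 ± 0.22 to 16 ± 0.82 CPM), and TBX15, MSX1, CDKN2A, SOX8 and BMP2 fell (adjusted p = 0.00125, and adjusted p = 0.344 with an estimated correlation). Of 35 HOX genes, 20 rose, such as HOXC13 (8.18 ± 0.27 to 24.3 ± 1.5 CPM), and HOXA13, HOXB4, HOXB7 and HOXB8 fell (adjusted p = 0.00584, and adjusted p = 0.288 with an estimated correlation). HOX genes overlap one another, so reads of neighbours may be mixed.

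Genes of axon guidance and neuronal adhesion also rose with EZH2i, 18 of 23 with 0 falling (median log2 fold change 1.23). The cell adhesion gene CNTN1 went from 2.65 ± 0.16 to 54.8 ± 1 CPM, 20.6-fold higher, and the semaphorins SEMA3C and SEMA5A from 0.481 ± 0.061 to 6.19 ± 0.53 CPM and from 0.224 ± 0.12 to 3.3 ± 0.42 CPM. The list passed camera (adjusted p = 6.1e-06, and adjusted p = 0.0472 with an estimated correlation). COL8A1, a collagen gene, rose 82.8-fold (0.597 ± 0.34 to 49.8 ± 2.1 CPM) and the receptor tyrosine kinase gene RET 73-fold (0.216 ± 0.057 to 15.9 ± 0.98 CPM). ADAMTSL2, DCHS2, UBASH3B, TCHH and SLC38A4 followed, at 59.7-, 49.8-, 27.5-, 18.1- and 17.9-fold. Among the largest falls, the gonadotropin-releasing hormone receptor gene GNRHR was 33.4-fold lower (11.6 ± 1.1 to 0.347 ± 0.13 CPM) and FATE1 19.7-fold lower. In the mesenchymal list 12 of 19 genes rose, such as fibronectin, FN1 (110 ± 4.4 to 751 ± 48 CPM), and SPARC, ACTA2 and CDH2 fell (adjusted p = 0.0114, and adjusted p = 0.142 with an estimated correlation).

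Genes of DNA replication, mitosis, the ribosome and the nuclear-encoded respiratory chain fell with EZH2i, and genes of 3 stress lists rose. Of 40 genes of DNA replication, 33 fell, such as RRM2 (243 ± 4 to 150 ± 4.5 CPM), and POLA1 rose (camera adjusted p = 3.95e-09, and adjusted p = 0.0648 with an estimated correlation). Of 41 mitotic genes, 32 fell, such as BIRC5 (221 ± 9 to 133 ± 2.2 CPM), and CENPF rose (adjusted p = 7.71e-09, and adjusted p = 0.142 with an estimated correlation). MKI67 was at 561 ± 74 CPM at baseline and 644 ± 53 CPM with EZH2i and did not pass. Nuclear genes of the respiratory chain fell in 33 of 34 cases and ribosomal protein genes in 46 of 50, with 0 rising in either list. Examples are ATP5F1A (497 ± 31 to 223 ± 9.4 CPM) and RPL35 (787 ± 59 to 395 ± 8.6 CPM). Both lists passed camera (adjusted p = 3.83e-13 and 5.76e-14), and with an estimated correlation their adjusted p was 0.212 and 0.272. Of 13 mitochondrially encoded mRNAs 5 rose and 0 fell (adjusted p = 0.0413, and adjusted p = 0.672 with an estimated correlation). That call was lost without baseline replicate 2 (camera adjusted p = 0.0659), baseline replicate 3 (0.12) or EZH2i replicate 3 (0.124). In the integrated stress response list 28 of 31 genes rose, such as CHAC1 (7.82 ± 0.47 to 38.7 ± 2.1 CPM) and NUPR1 (4.62 ± 0.37 to 21.6 ± 1.5 CPM), and PSPH and VLDLR fell (adjusted p = 8.02e-12, and adjusted p = 0.0472 with an estimated correlation). Of 21 endoplasmic reticulum chaperone genes 19 rose, such as HSPA5 (860 ± 24 to 1770 ± 38 CPM), and SYVN1 and ERN1 fell (adjusted p = 2.16e-07, and adjusted p = 0.167 with an estimated correlation). NRF2 targets rose in 17 of 20 cases, such as heme oxygenase, HMOX1 (30.9 ± 0.65 to 147 ± 2.9 CPM), and TALDO1 fell (adjusted p = 6.01e-06, and adjusted p = 0.15 with an estimated correlation). Of 24 genes of cholesterol synthesis and uptake 19 fell and 0 rose (camera adjusted p = 5.45e-07, and adjusted p = 0.0846 with an estimated correlation).

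Across the 20360 genes tested, 11778 differed between EZH2i and baseline, 6011 higher and 5767 lower. Of these, 2323 differed by more than 1.5-fold in a test against that fold, 1347 higher and 976 lower. Of 33 gene lists, 17 passed camera, and 3 did so with an estimated correlation: steroidogenic enzymes, integrated stress response and axon guidance. Adjusted over the list alone, the counts differed for mitotic genes (2 higher, 35 lower), ribosomal proteins (47 lower), zona glomerulosa genes (6 higher), other Polycomb targets (31 higher) and axon guidance (19 higher), and were the same for the other lists named here apart from AKR1C3.

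The second comparison asked what PRI-724 did, and steroidogenic genes fell again. HSD3B2 went from 78.5 ± 6.6 to 3.54 ± 0.22 CPM, 22-fold lower (log2 fold change -4.46 ± 0.10 SE, adjusted p = 4.12e-18, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). CYP17A1 fell 14.9-fold to 4.25 ± 0.16 CPM, STAR to 146 ± 10 CPM and CYP11A1 to 65 ± 0.58 CPM. Of 16 steroidogenic enzymes 15 fell and 0 rose, with a median log2 fold change of -2.04, and H6PD (-0.13) did not pass (camera adjusted p = 8.16e-10, and adjusted p = 0.0472 with an estimated correlation). NR5A1 fell to 323 ± 27 CPM, and MC2R fell 19.4-fold to 0.18 ± 0.059 CPM. NR0B1 was at 8.72 ± 0.96 CPM against 10.3 ± 1.2 CPM at baseline and did not pass. Of 16 adrenocortical identity genes 11 fell, including FATE1 (48.5-fold lower), and CITED2, HOXA5 and TBX3 rose (adjusted p = 0.00116, and adjusted p = 0.174 with an estimated correlation). In the zona glomerulosa list 9 genes fell and 5 rose, and the list did not pass (camera adjusted p = 0.206).

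Wnt targets rose with CBPi in 15 of 22 cases. CCND1 rose to 9.27 ± 0.27 CPM, 4.13-fold, NKD1 to 1020 ± 55 CPM, AXIN2 to 172 ± 3 CPM and LEF1 to 143 ± 7.2 CPM. BIRC5, the survivin gene, fell from 221 ± 9 to 106 ± 0.5 CPM, and TCF7, WIF1 and ISM1 fell as well (camera adjusted p = 8.65e-04, and adjusted p = 0.272 with an estimated correlation). CTNNB1 was at 1330 ± 24 CPM and did not pass (adjusted p = 0.154, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). CREBBP, which encodes CBP, rose from 121 ± 10 to 165 ± 12 CPM, and EP300, its paralogue, from 68 ± 4.3 to 83.8 ± 4.5 CPM. The HOX list (14 of 35 higher, 9 lower), the other Polycomb targets (18 of 50 higher, 14 lower) and axon guidance (9 of 23 higher, 4 lower) did not pass camera, with adjusted p of 0.551, 0.353 and 0.299. CNTN1 fell to 1.02 ± 0.26 CPM.

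Proliferation genes fell with CBPi in nearly every case tested. Of 41 mitotic genes 40 fell and 0 rose, such as AURKA (80 ± 1.2 to 36.8 ± 0.34 CPM) and PLK1 (160 ± 3.6 to 75.7 ± 1.9 CPM). Of 40 replication genes 37 fell and 0 rose, such as RRM2 (243 ± 4 to 93.9 ± 1.1 CPM). Both lists passed camera (adjusted p = 5.24e-18 and 3.48e-13, each with an adjusted p of 0.0472 with an estimated correlation). MKI67 fell from 561 ± 74 to 357 ± 6.4 CPM. Integrated stress response genes rose in 29 of 31 cases, with a median log2 fold change of 1.66, and PSPH and VLDLR fell (adjusted p = 4.39e-17, and adjusted p = 0.0472 with an estimated correlation). NUPR1 rose from 4.62 ± 0.37 to 47.7 ± 4.5 CPM and STC2 from 0.597 ± 0.038 to 6.23 ± 1.2 CPM. Cholesterol synthesis and uptake genes fell in 22 of 24 cases, and STARD4 and TM7SF2 rose (adjusted p = 1.72e-09, and adjusted p = 0.0472 with an estimated correlation). Of 21 endoplasmic reticulum chaperone genes 17 rose and 0 fell, such as XBP1 (58 ± 1.1 to 176 ± 5.3 CPM; adjusted p = 4.94e-08, and adjusted p = 0.15 with an estimated correlation). Of 20 NRF2 targets 14 rose, such as HMOX1 (30.9 ± 0.65 to 243 ± 11 CPM), and TALDO1, AKR1C1 and OSGIN1 fell (adjusted p = 0.00125, and adjusted p = 0.218 with an estimated correlation).

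Nuclear respiratory chain genes fell with CBPi in 33 of 34 cases (camera adjusted p = 3.68e-10, and adjusted p = 0.246 with an estimated correlation), such as CYC1 (155 ± 7 to 83.4 ± 8.9 CPM). Mitochondrially encoded mRNAs rose in 8 of 13 cases, such as MT-ND2 (1170 ± 180 to 4150 ± 540 CPM; adjusted p = 0.0108, and adjusted p = 0.632 with an estimated correlation). Ribosomal protein genes went both ways, 11 higher and 23 lower of 50, and the list did not pass (camera adjusted p = 0.11). Heat shock genes fell in 11 of 14 cases, such as HSPD1 (1160 ± 15 to 461 ± 24 CPM), and SERPINH1 rose (adjusted p = 0.00427, and adjusted p = 0.182 with an estimated correlation). In the mesenchymal list 13 of 19 genes rose, such as FN1 (110 ± 4.4 to 986 ± 34 CPM), and SPARC, ACTA2 and CDH2 fell (adjusted p = 0.00239, and adjusted p = 0.074 with an estimated correlation). Fibroblast markers fell in 6 of 8 cases and rose in 0, such as COL3A1 (15.7 ± 1.3 to 5.09 ± 0.49 CPM; adjusted p = 0.0267, and adjusted p = 0.15 with an estimated correlation). Among the largest rises were KCNN4, a potassium channel gene (0.216 ± 0.057 to 5.35 ± 1.2 CPM, 24.4-fold), DMGDH (20.8-fold), ADM2 (20.3-fold), GDF15 (15.3-fold), PAPPA2 (13.6-fold), INHBE (13.5-fold) and NIBAN1 (13.2-fold).

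In all, 11983 genes differed between CBPi and baseline, 6070 higher and 5913 lower, and 2491 differed by more than 1.5-fold, 1240 higher and 1251 lower. Of 33 lists 14 passed camera, and 5 did so with an estimated correlation: steroidogenic enzymes, both proliferation lists, cholesterol synthesis and integrated stress response. Adjusted over the list alone, counts differed for adrenocortical identity (12 lower), NRF2 targets (15 higher, 4 lower) and fibroblast markers (1 higher) among the lists named here.

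The third comparison asked what cAMP stimulation did, and steroidogenic genes rose. STAR went from 661 ± 8.8 to 1240 ± 43 CPM, 1.88-fold higher (log2 fold change 0.91 ± 0.05 SE, adjusted p = 9.21e-13, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). CYP17A1 rose 2.15-fold to 136 ± 2.3 CPM, HSD3B2 2.06-fold to 162 ± 2.8 CPM, CYP11A1 1.18-fold to 365 ± 16 CPM and MC2R 3.01-fold to 10.6 ± 1.3 CPM. CYP21A2, the 21-hydroxylase gene, rose 4.13-fold to 1270 ± 21 CPM. CYP11B1 and CYP11B2, which make cortisol and aldosterone, rose from 0.44 ± 0.016 to 7.2 ± 0.69 CPM and from 1.42 ± 0.44 to 10.2 ± 1.3 CPM. Of 16 steroidogenic enzymes 12 rose, and SULT2A1, AKR1C3, CYB5A and H6PD fell (camera adjusted p = 0.00584, and adjusted p = 0.216 with an estimated correlation). SULT2A1, the sulfotransferase that makes DHEA sulfate, fell 9.15-fold, from 74.2 ± 5.3 to 8.08 ± 0.8 CPM. NR5A1 rose 1.33-fold to 781 ± 29 CPM, and NR0B1 fell from 10.3 ± 1.2 to 3.04 ± 0.28 CPM. The adrenocortical identity list (8 of 16 higher, 5 lower) and the zona glomerulosa list (7 of 17 higher, 7 lower) did not pass, with camera adjusted p of 0.299 and 0.806, and the identity list had a median log2 fold change of 0.26 and a mean of -0.025. MRAP, which carries the ACTH receptor to the cell surface, fell from 2.55 ± 0.37 to 0.241 ± 0.032 CPM.

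Genes of the cAMP and CREB response rose with FSK in 19 of 27 cases. INHBA went from 4.11 ± 0.76 to 45.6 ± 2.4 CPM, 11.2-fold higher, the nuclear receptor gene NR4A1 from 325 ± 9.5 to 1100 ± 11 CPM, and EGR1 from 79.5 ± 9.7 to 306 ± 44 CPM. RGS2, PPARGC1A, SGK1, CREB3L1, PER1 and PRKAR1A fell (camera adjusted p = 1.02e-04, and adjusted p = 0.0577 with an estimated correlation). Cholesterol synthesis and uptake genes rose in 15 of 24 cases, such as STARD4 (148 ± 2.9 to 292 ± 5 CPM), and PMVK and INSIG1 fell (adjusted p = 0.00203, and adjusted p = 0.216 with an estimated correlation). Fatty acid synthesis genes fell in 8 of 15 cases, such as SREBF1 (88.9 ± 3.8 to 29.3 ± 1.4 CPM), and ACLY and FASN rose (adjusted p = 0.0261, and adjusted p = 0.245 with an estimated correlation). VGF, a secreted neuropeptide precursor, reached 8580 ± 420 CPM from 434 ± 20 CPM. MMP10, ADGRD1, GCNA, AREG, IL7R, PMEPA1 and GDF15 were the other largest rises, at 36.2-, 30.8-, 28.9-, 24.4-, 23.3-, 18.9- and 15.8-fold. The largest falls included KCNC2, a potassium channel gene (9.64 ± 1.5 to 0.368 ± 0.11 CPM), PROK1, SFRP4, COLCA1, SCN1A and ATOH8.

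Wnt targets fell with FSK in 15 of 22 cases, such as AXIN2 (103 ± 4.6 to 46.1 ± 1.1 CPM), LEF1 (93.1 ± 2.9 to 58.7 ± 1.8 CPM), NOTUM (43 ± 2.6 to 8.2 ± 0.64 CPM) and LGR5 (12.7 ± 0.44 to 2.66 ± 0.17 CPM). NKD2, TCF7, MYC, DKK1 and TBX3 rose (camera adjusted p = 1.01e-04, and adjusted p = 0.218 with an estimated correlation). CTNNB1 was at 1250 ± 17 CPM against 1280 ± 23 CPM and did not pass (adjusted p = 0.493, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The Wnt ligand gene WNT4 fell from 290 ± 10 to 74.7 ± 2 CPM. Mitotic genes fell in 40 of 41 cases, such as NUSAP1 (153 ± 0.38 to 78.3 ± 2.2 CPM; adjusted p = 6.83e-16, and adjusted p = 0.0472 with an estimated correlation). Replication genes fell in 20 of 40 cases, such as TYMS (209 ± 4.4 to 137 ± 5.6 CPM), and EXO1, POLA1, TIPIN, CDT1 and CDC6 rose (adjusted p = 0.00636, and adjusted p = 0.272 with an estimated correlation). Integrated stress response genes rose in 26 of 31 cases, such as TRIB3 (71.2 ± 1.6 to 493 ± 15 CPM), and VLDLR, NUPR1 and PSPH fell (adjusted p = 8.98e-12, and adjusted p = 0.0472 with an estimated correlation). Endoplasmic reticulum chaperones rose in 18 of 21 cases with 0 falling, such as HSPA5 (860 ± 24 to 1660 ± 22 CPM; adjusted p = 2.48e-08, and adjusted p = 0.15 with an estimated correlation). Ribosomal protein genes rose in 25 of 50 cases with 0 falling, and the change was small, with a median log2 fold change of 0.14 (adjusted p = 0.0014, and adjusted p = 0.646 with an estimated correlation). With libraries scaled by their size only, the median over all genes was -0.054, against 0.015 here. A count of such small rises may therefore depend on the scaling.

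In all, 10299 genes differed between FSK and baseline, 5197 higher and 5102 lower, and 2401 differed by more than 1.5-fold, 1088 higher and 1313 lower. With libraries scaled by their size only, 39.7% of the changed genes were higher, against 50.5% here. Of 33 lists 13 passed camera, and 2 did so with an estimated correlation: mitotic genes and integrated stress response. Adjusted over the list alone, counts differed for Wnt targets (16 lower), replication genes (21 lower) and chaperones (19 higher) among the lists named here.

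**Figure D2:**
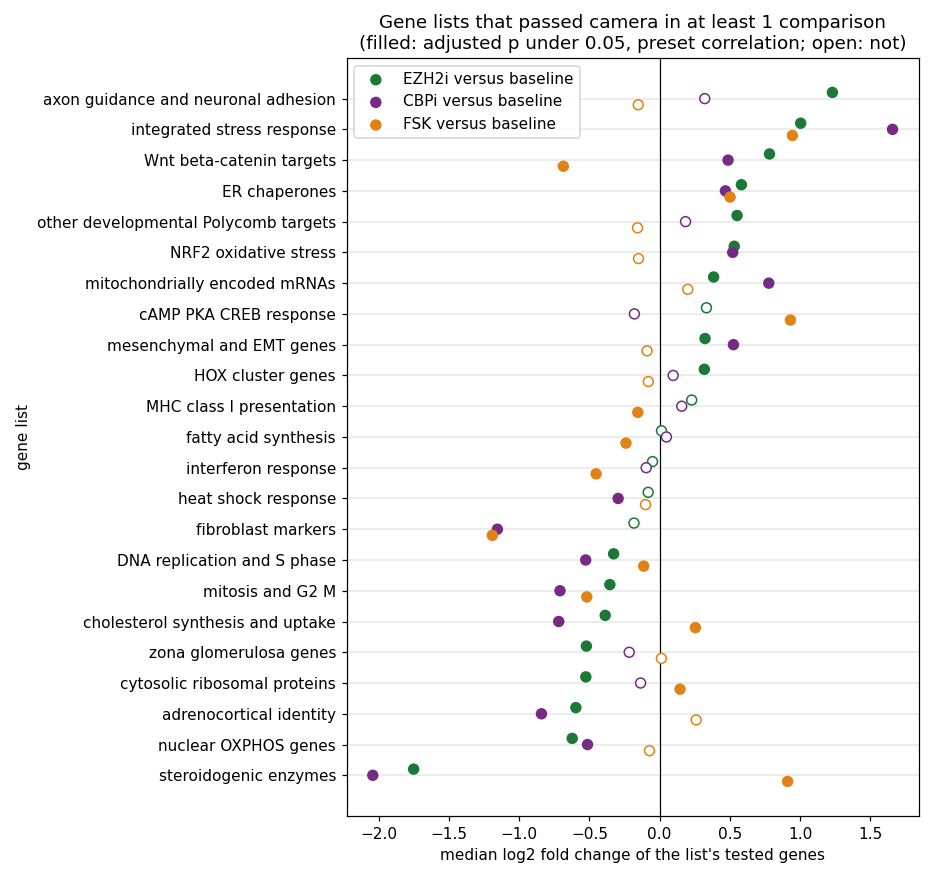
Median log2 fold change of the tested genes of 23 gene lists in each comparison with baseline, filled where the list passed camera with the preset correlation. Steroidogenic enzymes had medians of -1.75 with EZH2i, -2.04 with CBPi and 0.91 with FSK, and integrated stress response genes were higher in all 3 comparisons (1.00, 1.66 and 0.94).

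Several of these values are uncertain because reads can be shared. The file holds fractional counts, as arise when a read is split between places or genes. HSD3B2 has a close paralogue in HSD3B1, CYP21A2 a near-identical pseudogene, and CYP11B1 and CYP11B2 resemble each other. AKR1C1 and AKR1C3, HSPD1, mitochondrial genes with nuclear copies, and ribosomal protein genes with pseudogenes are uncertain for the same reason. Strand handling is not given in the sources used here, so reads of a gene and of an overlapping antisense gene cannot be separated. With CBPi, CYP11B1 had raw counts of 0, 4 and 0 and CYP11B2 of 1, 7 and 2, so no fold is given for these. Some folds that are given also rest on few reads. With CBPi, MC2R had raw counts of 5, 3 and 5 and FATE1 of 3, 7 and 3, so the sizes of their folds are uncertain. The same holds for genes under 1 CPM in either group, such as RET, COL8A1, KCNN4 and GNRHR. On GRCh38, in the GENCODE annotation, HSD3B2 (ENSG00000203859) lies on chromosome 1 from 119414931 to 119423035, STAR (ENSG00000147465) on chromosome 8 from 38143649 to 38151265, and CYP17A1 (ENSG00000148795) on chromosome 10 from 102830531 to 102837533. AXIN2 (ENSG00000168646) lies on chromosome 17 from 65528563 to 65561647, COL8A1 (ENSG00000144810) on chromosome 3 from 99638475 to 99799226, and VGF (ENSG00000128564) on chromosome 7 from 101162509 to 101165593. All 6 are protein-coding genes, and each value covers the whole gene.

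Calls were then compared between treatments. EZH2i and CBPi changed 8188 genes in the same direction, 4083 higher and 4105 lower in both, and 555 in opposite directions. Independent lists of the same sizes would share 3467 in the same and 3465 in opposite directions. EZH2i and FSK shared 4430 genes in the same direction and 2468 in opposite directions (independent lists: 2979 and 2978), and CBPi and FSK 5199 and 1994 (3031 and 3030). Across genes, the log2 fold changes of EZH2i and CBPi had a correlation of 0.69 and a covariance of 0.355, EZH2i and FSK 0.19 and 0.105, and CBPi and FSK 0.33 and 0.177. The 3 comparisons share their baseline libraries. In 20 simulated sets of unchanged groups with a shared baseline, all drawn from the same means, the mean number of shared calls was 0, the correlations averaged 0.54, 0.53 and 0.51, and the covariances 0.0267, 0.0263 and 0.0266. So the shared baseline alone gives a sizeable correlation where no group has changed, and a correlation by itself does not measure a shared effect. The covariance that it gave was smaller than the observed one in each pair, 0.0267 against 0.355 for EZH2i and CBPi. After the simulated covariance was subtracted, 0.328, 0.0787 and 0.15 were left. The simulation leaves out real effects and the independent lists leave out the shared controls. The controls were not split, since 3 libraries do not give each side 2, so part of the excess in shared calls may come from them.

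Direct tests between the treatments gave the sizes of the differences. EZH2i and CBPi differed in 8930 genes (4408 higher and 4522 lower with EZH2i), and 54.9% of them were higher with libraries scaled by their size only, against 49.4% here. HSD3B2 (3.94 ± 0.75 and 3.54 ± 0.22 CPM) did not pass, with a log2 difference of 0.15 ± 0.14 (SE). CYP17A1 was 3.09-fold higher with EZH2i, and CYP21A2 was lower (log2 difference -1.11). AXIN2 and LEF1 were higher with EZH2i by 0.17 and 0.47 on the log2 scale, and CTNNB1 was lower (-0.46). COL8A1, RET, CNTN1, SLC38A4 and ANKRD33B were the most raised with EZH2i over CBPi, from 107-fold for COL8A1 to 13.8-fold for ANKRD33B. KLF2, DMGDH, ABCA1, INHBE and INHBA were the most lowered among named genes that differed. Integrated stress response genes were lower with EZH2i than with CBPi in 30 of 31 cases, and 40 of 41 mitotic genes were higher (camera adjusted p = 4.77e-18 and 4.44e-17, and adjusted p = 0.0526 and 0.0895 with an estimated correlation). Other Polycomb targets were higher with EZH2i than with CBPi in 21 of 50 cases and lower in 5 (adjusted p = 0.0021, and adjusted p = 0.378 with an estimated correlation).

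EZH2i and FSK differed in 12541 genes (6175 higher and 6366 lower with EZH2i), and CBPi and FSK in 11972 (5971 higher and 6001 lower with CBPi). With libraries scaled by their size only, 59.1% and 57.1% of the changed genes were higher than with FSK, against 49.2% and 49.9% here. HSD3B2 was lower than with FSK by log2 differences of -5.35 with EZH2i and -5.50 with CBPi, and STAR of -2.94 and -3.09. AXIN2 was 4.19-fold and 3.73-fold higher than with FSK, and NR0B1 6.69-fold and 2.88-fold. Wnt targets were higher than with FSK in 17 of 22 cases with EZH2i and 16 of 22 with CBPi, and lower in 5 and 3 (camera adjusted p = 1.97e-06 and 4.76e-06, and adjusted p = 0.21 and 0.231 with an estimated correlation). Steroidogenic enzymes were lower than with FSK in 12 and 13 of 16 cases and higher in 1 and 2 (adjusted p = 4.95e-06 and 1.1e-06, and adjusted p = 0.0939 and 0.0895 with an estimated correlation). DLX3 was among the most raised genes over FSK with both inhibitors (75.5-fold with EZH2i and 37-fold with CBPi), and SPRR1B, FAM166B, ADGRD1 and UTS2 were among the most lowered. No list in the 3 direct comparisons passed camera with an estimated correlation.

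**Figure D3:**
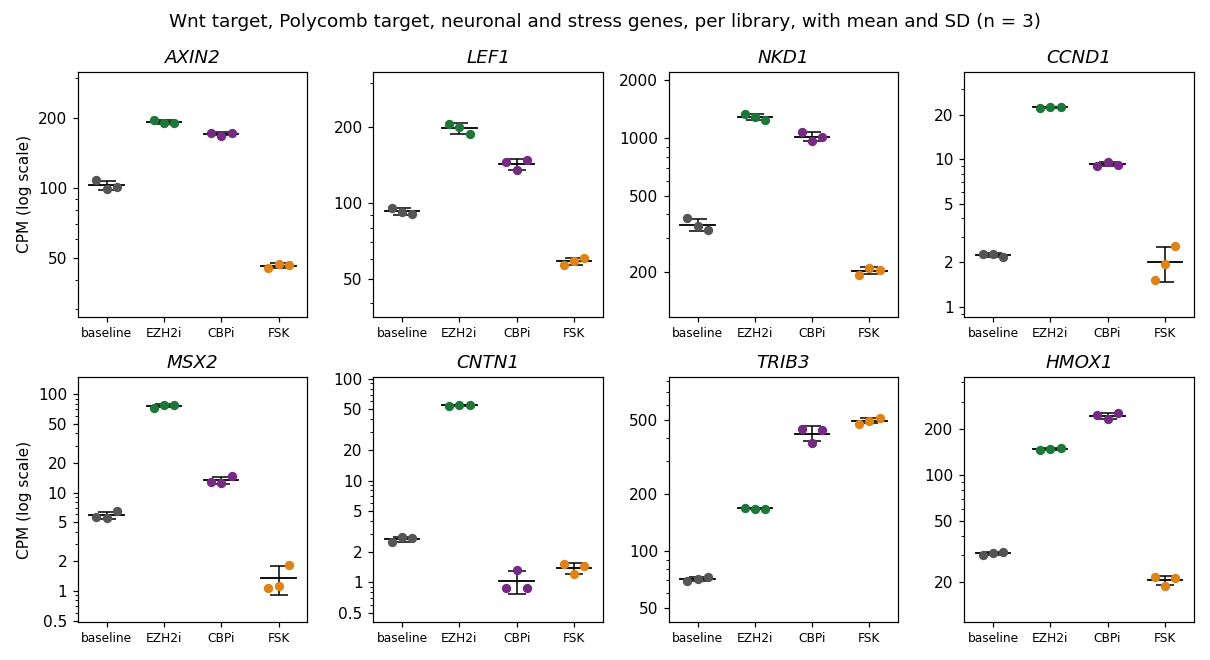
CPM of 8 genes on log scales, 1 point per library, with the mean and SD of each group (n = 3). AXIN2 and LEF1 lay above baseline with EZH2i and CBPi and below it with FSK, while CNTN1 reached 54.8 ± 1 CPM with EZH2i and 1.02 ± 0.26 CPM with CBPi.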

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

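The alternatives were planned before the data were examined, except leaving out libraries for lists and overlaps and leaving out the 2 libraries farthest from their groups, which were chosen after the results were seen. The 6 counts of genes changed stayed within 1.5 times under 21 settings: 10546 to 12420 for EZH2i, 10854 to 12220 for CBPi and 9186 to 10959 for FSK against baseline, 7674 to 9107 for EZH2i versus CBPi, 11541 to 13241 for EZH2i versus FSK and 10913 to 12319 for CBPi versus FSK. At a fold threshold of 2, 799, 737 and 1072 genes passed. Among genes changed by more than 1.5-fold, 1192 were shared in the same direction by EZH2i and CBPi, 477 by EZH2i and FSK and 652 by CBPi and FSK, and 12, 289 and 203 in opposite directions. The lists passing camera, 44 over the 3 comparisons, became 10 with an estimated correlation (3, 5 and 2). Camera sets a list against the other genes, while fry asks whether a list changed at all, which most lists do where 50.6% to 58.9% of all genes changed. Fry called 83 lists with direction (29, 28 and 26) and 96 without (32 in each), so these counts answer another question.

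No list called by camera reversed. Lists that were not called and changed direction were fatty acid synthesis with CBPi (fry adjusted p = 0.00115; 0.905 to 0.991 with 1 library left out), fibroblast markers with EZH2i (fry 0.908), neuroendocrine markers with FSK (fry 0.0529) and the xenobiotic response with FSK (fry 0.539; library size only 0.929). With 1 library left out, epithelial markers (0.794 to 0.997), immune markers (0.661 to 0.94) and p53 targets (0.905 to 0.993) with CBPi and immune markers with FSK (0.519 to 0.978) also did. The call for mitochondrially encoded mRNAs with EZH2i was lost without baseline replicate 2 (adjusted p = 0.0659), baseline replicate 3 (0.12) or EZH2i replicate 3 (0.124), and by fry (0.05). With library size only, fibroblast markers with FSK lost their call (0.0895) and epithelial markers with FSK gained one (0.0336). The xenobiotic response with EZH2i gained a call with any 1 of the 12 libraries left out (0.0158 to 0.0477), and cholesterol efflux with CBPi without baseline replicate 1 (0.0383), baseline replicate 3 (0.0448), EZH2i replicate 2 (0.0434), CBPi replicate 2 (0.0331) or FSK replicate 1 (0.0362). Calls were also gained without baseline replicate 1 for ribosomal proteins with CBPi (0.0249) and epithelial markers with FSK (0.0329), without baseline replicate 3 for imprinted genes with CBPi (0.0421) and without CBPi replicate 2 for the interferon response with CBPi (0.0293). Each fit with 1 library left out filtered the genes anew, so the genes tested changed as well as the libraries. The xenobiotic call with EZH2i was gained also without CBPi or FSK libraries, which lie outside that comparison. These calls therefore cannot be credited to single libraries, and which of the changes moved them was not tested. No paired analysis was possible because the labels give no replicate numbers; those used here follow the order of deposit and only name the libraries.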

Other observations

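With FSK, 22 of 38 interferon response genes fell, such as IFI44L (12.7 ± 0.71 to 4.47 ± 0.41 CPM, SD, n = 3), and 3 rose, PARP12 and STAT2 among them (camera adjusted p = 1.48e-04, and adjusted p = 0.196 with an estimated correlation). MHC class I presentation genes fell in 12 of 19 cases with FSK, and CALR rose (camera adjusted p = 0.00532, and adjusted p = 0.245 with an estimated correlation). Fibroblast markers fell in 6 of 8 cases with FSK, such as COL3A1 (15.7 ± 1.3 to 3.48 ± 0.45 CPM), with a median log2 fold change of -1.19 and a mean of -0.19 over the list, while LUM rose from 0.0397 ± 0.037 to 4.61 ± 0.75 CPM and DCN rose too (camera adjusted p = 0.0419, adjusted p = 0.0895 with library size only, and adjusted p = 0.176 with an estimated correlation). The neurofilament genes NEFL and NEFM fell with FSK from 113 ± 3.9 to 21.1 ± 2.6 CPM and from 30.5 ± 0.66 to 9.73 ± 1.4 CPM. In their neuroendocrine list 6 of 11 genes rose and 4 fell. With a median log2 fold change of 0.39 and a mean of -0.05, the list did not pass (camera adjusted p = 0.777).

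The aryl hydrocarbon receptor target CYP1A1 rose from 10.1 ± 1.3 CPM to 111 ± 3.1 with EZH2i, 38.6 ± 0.95 with CBPi and 16.7 ± 0.79 with FSK, and the xenobiotic list did not pass in any of these (camera adjusted p = 0.0529, 0.227 and 0.941; with FSK its median log2 fold change was -0.18 and its mean 0.005). Among BCL2 family genes, the proapoptotic BMF rose from 30.1 ± 0.4 CPM to 161 ± 8.3 with EZH2i and 78.7 ± 1.2 with CBPi and fell to 3.01 ± 0.23 with FSK, while the survival gene MCL1 rose from 259 ± 3.8 to 650 ± 11 CPM with FSK. The list did not pass (camera adjusted p = 0.252, 0.232 and 0.662). The cholesterol exporter ABCA1 rose with CBPi from 11 ± 1.5 to 42.2 ± 4.1 CPM, and its list of 9 did not pass (camera adjusted p = 0.0519). IGF2 was at 3770 ± 220 CPM at baseline, 4130 ± 51 with EZH2i, 3400 ± 540 with CBPi and 3450 ± 310 with FSK and did not pass. GRB10, another imprinted gene, rose from 38.1 ± 0.57 CPM to 135 ± 9.8, 99.8 ± 0.95 and 73.9 ± 2.9.

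Tests of the 3 patterns that follow were planned before their results were seen, except the tests of unusual baseline libraries as the whole cause, which were chosen after the stress results were seen, and the sizes of the 2 trends, which were looked at after the corrected medians. Ribosomal protein and respiratory chain genes were lower with EZH2i, with a median log2 fold change of -0.55 over 84 genes. After each library's trend on gene length was removed it was -0.53 (-0.57 to -0.47), and after the trend on GC content -0.56 (-0.6 to -0.52). The ranges in brackets, here and for the patterns that follow, come from 2000 resamplings of the member genes. They describe the spread between genes, not between replicate cultures, and can be too narrow for genes that move together. Removing the trend on GC content moved these genes by only -0.05 to 0.01, so a near unchanged median was expected and the evidence is that this trend is too small to give their fall, while removing the trend on length moved them by -0.22 to 0.17. The highest median under 3 other scalings was -0.53. Under these scalings the median over all genes was 0.018 to 0.046, so little change in the members was to be foreseen here too. The values argue against the length of the annotated gene, GC content and the choice among these scalings as the whole cause. The length used was the one deposited per gene, with a median of 3056 for the members and 4048 for all genes tested. It need not be the length of the transcripts expressed, so a bias on transcript length was not tested. Respiratory chain genes fell with CBPi too (median log2 fold change -0.514), so that part was not particular to EZH2i. With FSK their median was -0.073. Mitotic genes fell more with CBPi (median -0.71) and FSK (-0.519) than with EZH2i (-0.355). Ribosomal protein genes had medians of -0.136 with CBPi and 0.145 with FSK, so they did not follow the mitotic genes across treatments. Growth was not measured, and whether EZH2 inhibition or slower growth gave the pattern was not tested.

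Neuronal surface genes were higher with EZH2i (median log2 fold change 1.21). The median was 0.97 (0.54 to 1.53) after the trend on gene length was removed, and 1.23 (0.68 to 1.44) with every library thinned to the smallest total. The first value argues against the length of the annotated gene as the whole cause. Thinning leaves the expected CPM unchanged, and the genes kept were those that passed the filter at full depth. A near unchanged median was therefore to be foreseen. The thinning does not show whether the deeper EZH2i libraries let weakly expressed genes enter the test. Release of Polycomb silencing is a candidate explanation, and no histone mark was measured.

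Integrated stress response genes were higher in all 3 treatments. Unusual baseline libraries as the whole cause would make the treatments equal, and CBPi exceeded FSK by a median log2 difference of 0.59 (0.46 to 1.05), which argues against it for CBPi. Between EZH2i and FSK the median difference was -0.09 (-0.27 to 0.03), and 24 of the 31 genes differed, 9 higher and 15 lower with EZH2i, where 61.6% of all genes tested differed. For these 2 treatments a shared response, for example to the doses used, and unusual baseline libraries cannot be told apart, since the treatments share their 3 controls and the members go both ways. The lowest median without 1 baseline library was 0.92, which argues against a single baseline library.

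The libraries of each pair of groups were also split in the 10 ways that 6 libraries allow, and 10 splits are too few for a share under 0.05. For genes changed, only 1 of the 10, the real split, gave as many in each comparison: 12287 for EZH2i, 11118 for CBPi and 10361 for FSK against baseline, 8465 for EZH2i versus CBPi, 12864 for EZH2i versus FSK and 11057 for CBPi versus FSK. The highest other split gave 0 in each by edgeR at adjusted p under 0.05. Every other split mixes the 2 groups, so their difference enters the spread within each side and few calls can be made. The 0 therefore does not show what chance alone gives. For genes changed by more than 1.5-fold it was again 1 of 10, with 2512, 2305 and 2393 for EZH2i, CBPi and FSK and 0 in the highest other. For gene lists passing, 2 of 10 splits gave as many as the real 16 with EZH2i, where the highest other gave 16. With CBPi and FSK 1 of 10 did, with 15 and 12 in the real split and 14 and 11 in the highest other. The mixed splits keep part of the difference between the groups, so these list counts do not show it either.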
